A study of Mus musculus with 11 samples.

How the data were processed

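Bulk RNA-seq of the aortic arch at postnatal day 11 was compared between 5 WT and 6 Het mice. Per the labels' protocols, RNA was extracted with TriPure and PureLink, unstranded Nextera XT libraries were sequenced as single reads of 75 nt on a NextSeq 500, and the pooled libraries were run on 2 separate runs. The files hold 1 column per sample, so the runs cannot be separated. The submitters' processing notes name STAR 2.5.2a, DESeq2, edgeR, limma and the GRCm38 build, without the role of each. The counter and the annotation are not given in the sources used here.

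The deposited count table, made by the authors, holds whole numbers for 48733 rows, of which 48709 are mouse genes and 24 are spike-in or transgene sequences. The latter held 4 to 11 counts per library, at most 8.1e-05 percent of the total, and were not used. A second deposited count table holds 19629 of these rows with identical values; the rows it keeps have a highest count of at least 6 in some library and those it leaves out of at most 5. Another table is named as TMM-normalized CPM; this deposited signal sums to 966683 to 1026470 per library, and it served only for an alternative test. Symbols and coordinates were matched for 48349 of the mouse gene IDs in GENCODE M21 (GRCm38, positions counted from 1), and 360 IDs had none. Because the libraries do not mark strand, reads of a gene and of one that overlaps it on the other strand cannot be told apart, and genes with near-identical copies, such as the globins and MHC genes, are uncertain where counting could split them.

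Each library was assigned to WT or Het from its label. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 14757, and scaled by TMM factors of 0.979 to 1.031. CPM values in the text use these factors, except those of Xist and Ddx3y, which are CPM of the unscaled total counts. Het was tested against WT by edgeR's robust quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) in all 11 libraries, without covariates, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The standard error of a log2 fold change is its size divided by the square root of F. The common biological coefficient of variation was 0.215, and the median log2 fold change of all tested genes was -0.0046. Counting intervals and floors cover counting error only.

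The tests, 21 pathway lists, 23 marker lists and the rule for named genes were fixed before the data were examined. Lists with at least 3 tested members, 41 of 44, were tested by limma's camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the 41 lists, and again with an estimated correlation; fry was run beside it. The pathway lists cover TGF-beta ligands and response, BMP response, contractile, collagen, elastic fibre, basement membrane, proteoglycan, protease, cytokine, interferon, cell cycle, immediate early, unfolded protein response, Notch, vasoactive and metabolic genes. The rule named, among genes past the threshold with a mean of at least 1 CPM, the 8 highest and 8 lowest log2 fold changes and the 6 smallest p per direction, the 2 smallest adjusted p of each list, and a fixed set that includes Tgfbr2; predicted genes were passed over. Some genes given by the rule were left out of the text after their values were seen, to keep it short or because leaving out 1 library ended their call, and a few list members are not analysed singly here. Lama2, Snai2, Id3, Bmp4, H2-Ab1, H2-Eb1, H2-DMa, Ciita, Igf1, Igfbp4, Igfbp7, Sost, Sfrp1, Frzb, Dkk2 and Spry4 were named after their values were seen.

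Alternatives were other scalings (RLE and upper quartile), DESeq2 1.42.0, limma voom with and without sample weights, limma trend on the deposited CPM signal with pseudocounts of 1 and 0.5, other filters, a replicate block, a relaxed threshold of 0.1, covariates for sex, skeletal muscle, brown fat and T cell scores, surrogate variables (sva 3.50.0), and each library left out in turn. The sex score is the mean log2 CPM of Ddx3y, Eif2s3y, Kdm5d and Uty minus that of Xist. Chosen after seeing the data were the number in the column names as a covariate, the libraries with at least 100 Xist counts alone, the fit without WT 1 and WT 2, DESeq2 with the sex score, the estimated correlation in the fits beside that of all libraries, and, for the cell cycle genes, a pan-leukocyte score as a covariate.

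The tests were checked on simulated counts for Het against WT with 14757 genes. The edgeR test recovered 23.9 percent of 67 genes changed 1.5-fold, 65.7 percent of 67 changed 2-fold and 90.9 percent of 66 changed 4-fold, with 7 false among 127 calls, and called 0 genes where nothing was changed. Camera called both lists that were shifted by 0.5 log2 and 0 others of the 41. This does not show how specific camera is in the real libraries. Splits of these other than Het against WT called a median of 6 lists and at most 16. The preset correlation was 0.01, while the estimated one was 0.013 for TGF-beta response, 0.469 for cell cycle and 0.925 for mitochondrially encoded genes.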

Results

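RNA was sequenced in bulk from aortic arches of mice at postnatal day 11. The labels name vascular smooth muscle and endothelial cells as the cell type. Of the 11 libraries, 5 came from wild-type littermates (WT 1 to 5) and 6 from mice heterozygous for the G357W substitution in Tgfbr2, a model of Loeys-Dietz syndrome type II (Het 1 to 6). Loeys-Dietz syndrome is an inherited disorder of connective tissue with aneurysms of the aorta, and Tgfbr2 encodes the type II receptor for TGF-beta. The series description counts 6 Het mice and 5 WT littermates, so each library was taken as 1 animal. The labels give no more about the animals than that. Total counts per library were 13113467 to 19327935, with a mean of 15245411 ± 2516267 in WT (SD, n = 5) and 14667075 ± 2182109 in Het (SD, n = 6). Between 19988 and 21350 genes had a count in each library, and 3 counts, the upper limit that a count of 0 allows, were 0.155 to 0.229 CPM. Acta2, the smooth muscle actin, was the most abundant gene in every WT library and in Het 1, and Eln, which encodes elastin, in Het 2 to 6.

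The sex of the mice is not in the labels, and sex-linked genes differed between the groups. Xist, which is expressed from the inactive X chromosome, lay at 58.83 to 80.15 CPM in all 5 WT libraries and in Het 1 and Het 2. It was at most 0.75 CPM in Het 3 to 6. The Y-linked gene Ddx3y lay at 88.15 to 107.98 CPM in Het 3 to 6 and had 0 counts in the other 7 libraries. WT therefore held Xist-positive libraries only, and no WT library stands beside the 4 Y-positive Het libraries.

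**Figure D1:**
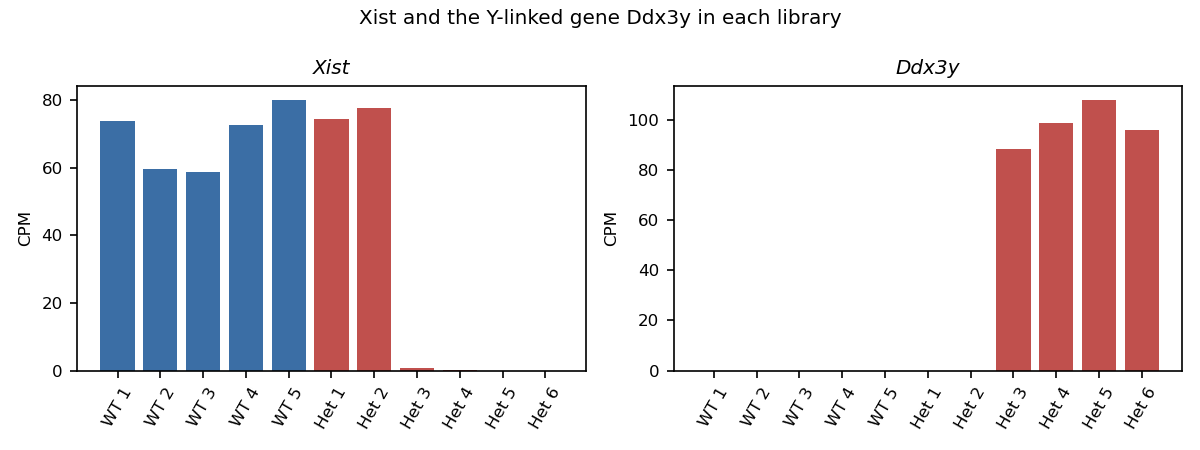
Xist and Ddx3y in CPM, 1 bar per library, for WT 1 to 5 and Het 1 to 6. Xist is high in the 5 WT libraries and in Het 1 and 2, and Ddx3y is high in Het 3 to 6.

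The targeted gene was measured first. Tgfbr2 (ENSMUSG00000032440, a protein-coding gene at 116084293 to 116175360 on chromosome 9 of GRCm38) was at 41.3 ± 4.29 CPM in WT (SD, n = 5) and 39.0 ± 8.22 CPM in Het (SD, n = 6). The log2 fold change of Het against WT was -0.085 ± 0.13 (SE), with an adjusted p of 0.79 by edgeR's quasi-likelihood test. No difference in transcript level was detected between the groups. The Het libraries were spread widely: Het 2, 4, 5 and 6 lay at 30.9 to 35.7 CPM, below every WT library (lowest 38.3). Het 1 and Het 3 lay at 47.1 and 51.4 CPM. Counts per gene do not separate the mutant from the wild-type allele, so this level does not check the genotype labels.

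The comparison of Het with WT asks how the young aortic arch differs in expression when 1 Tgfbr2 allele is mutant. The genes that rose with the smallest p encode matrix and cell surface proteins and a signalling inhibitor. Ccn3, a matricellular protein of the CCN family, went from 119.5 ± 12.9 CPM in WT to 524.8 ± 99.2 CPM in Het (log2 fold change 2.13 ± 0.13, SE, adjusted p = 3.99e-07). Acan, the large proteoglycan aggrecan, went from 5.55 ± 2.46 to 47.9 ± 12.5 CPM (log2 fold change 3.12 ± 0.25, adjusted p = 6.28e-06). Tnc, the matricellular protein tenascin C, rose by 1.55 ± 0.14 on the log2 scale, Ptprz1, a receptor tyrosine phosphatase, by 1.17 ± 0.11, and Lama5, a laminin chain, by 0.91 ± 0.09. Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, rose by 1.06 ± 0.10. Each of these 6 genes was higher in all 6 Het libraries than in any WT library.

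The genes that fell with the smallest p included members of the MHC class II pathway, a Wnt inhibitor and a potassium channel. Kcnj15, an inwardly rectifying potassium channel, went from 65.2 ± 8.13 CPM in WT to 17.8 ± 2.68 CPM in Het (log2 fold change -1.87 ± 0.12, adjusted p = 3.99e-07). Wif1, a secreted inhibitor of Wnt ligands, fell by 1.98 ± 0.15 on the log2 scale and Ggt5, a gamma-glutamyltransferase, by 2.05 ± 0.16. Cd74, the invariant chain of MHC class II, went from 403 ± 91.1 to 108 ± 18.7 CPM (log2 fold change -1.90 ± 0.15, adjusted p = 4.19e-06). H2-Aa fell by 1.75 ± 0.14 and H2-DMb1 by 1.46 ± 0.12. Each of these 6 genes was lower in all 6 Het libraries than in any WT library.

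**Figure D2:**
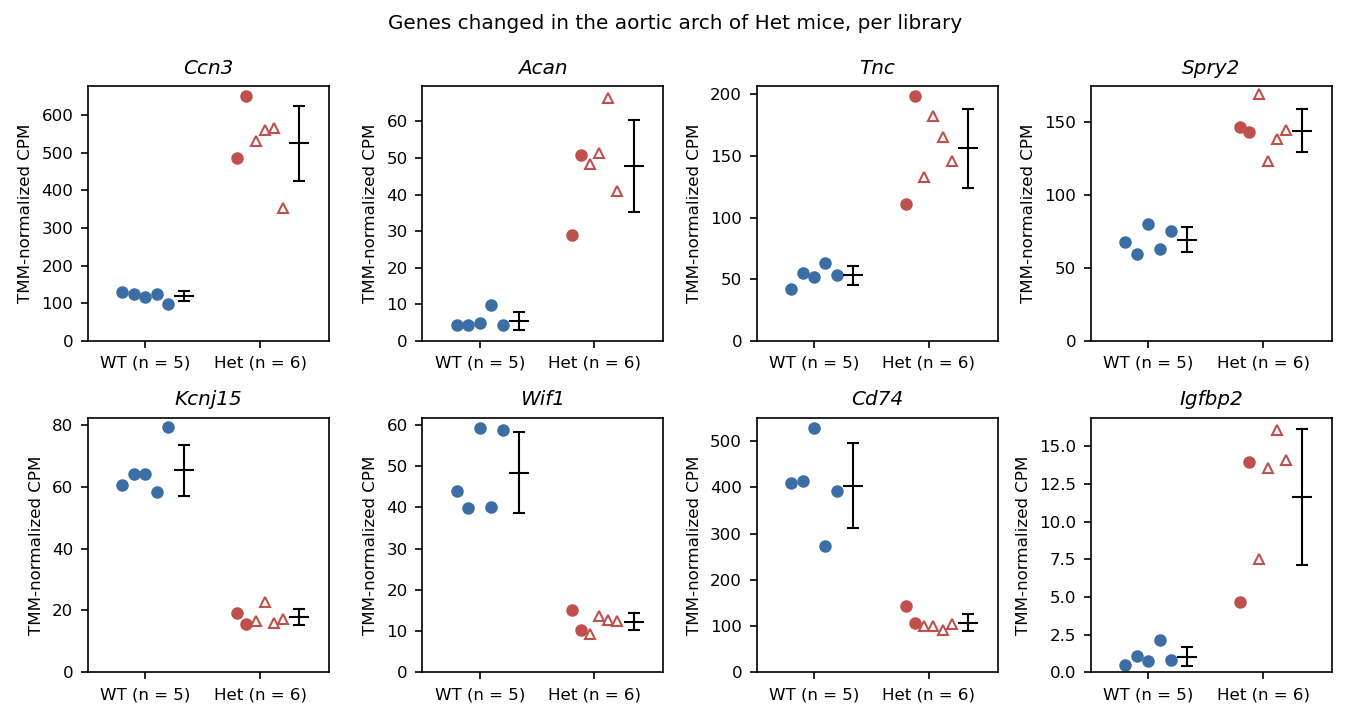
CPM per library of Ccn3, Acan, Tnc, Spry2, Kcnj15, Wif1, Cd74 and Igfbp2 in 5 WT and 6 Het libraries. Filled circles are Xist-positive libraries, open triangles Y-positive ones, and black bars the mean ± SD; the groups do not overlap for any of the 8 genes.

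Among the largest fold changes were several genes of low abundance. Igfbp2, a binding protein of insulin-like growth factors, went from 1.05 ± 0.641 to 11.6 ± 4.48 CPM (log2 fold change 3.48 ± 0.39, adjusted p = 1.21e-04). Ahsg, which encodes fetuin-A, rose by 2.64 ± 0.42, Gria4, a glutamate receptor subunit, by 2.55 ± 0.44, and Adcy1, an adenylyl cyclase, by 2.47 ± 0.27 on the log2 scale. The long noncoding RNA Sox2ot fell by 2.89 ± 0.33, Tnni2, a troponin of fast skeletal muscle, by 2.86 ± 0.51, and Chrm2, a muscarinic acetylcholine receptor, by 2.73 ± 0.38. Nppc, the precursor of C-type natriuretic peptide, fell by 2.46 ± 0.33 and Atp10b, a phospholipid-transporting ATPase, by 2.36 ± 0.42. The sizes of several of these changes moved with the processing by more than their SE. Over all settings the values were 1.21 to 2.84 for Gria4 (mean 0.386 CPM in WT) and 1.70 to 3.07 for Ahsg. They were -3.31 to -1.33 for Atp10b, -3.15 to -1.39 for Tnni2 and -2.72 to -1.60 for Nppc.

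In all, 742 of 14757 tested genes passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, of which 391 rose and 351 fell. Of these, 106 rose and 102 fell by more than 2-fold, and 703 were protein coding. With a sex score built from Xist and 4 Y-linked genes as a covariate, 122 genes passed, 121 of them among the 742. In the 7 Xist-positive libraries alone, 5 WT against 2 Het, 34 passed, all among the 742. All 742 genes kept their direction in both fits; the median ratio of their log2 fold changes to those from all libraries was 0.945 with the score and 0.955 in the Xist-positive libraries, while their standard errors were larger by median factors of 1.364 and 1.463. The genes were chosen in the 11 libraries, which hold those 7, so the kept directions and ratios are not an independent test. Of the named genes above, Nppc, Chrm2 and Tnni2 missed the threshold with the sex score (adjusted p = 0.0585, 0.0791 and 0.184). Of the 58 genes named in the text that passed, 30 passed with the sex score and 19 in the Xist-positive libraries. Leaving out WT 2 lowered the count to 465. A number in the deposited column names, 6 or 7, is not explained in the labels; with it as a covariate 415 genes passed, and 443 passed without WT 1 and WT 2, which lay apart on the first principal component.

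**Figure D3:**
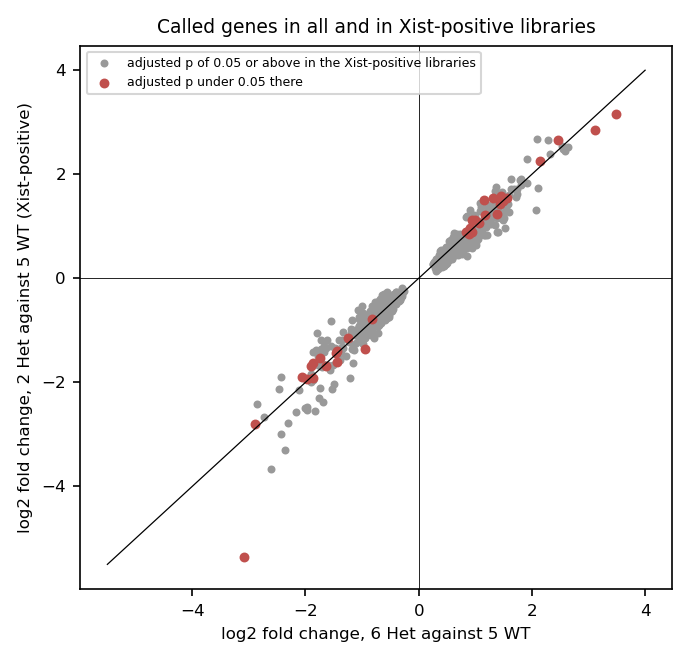
Log2 fold change (Het minus WT) of the 742 called genes in all 11 libraries (x axis) against the 7 Xist-positive libraries, 5 WT and 2 Het (y axis), 1 point per gene, with the line of equality. The genes past an adjusted p of 0.05 in the Xist-positive libraries, 34 of the 742, are red.

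Genes of the basement membrane, the sheet of laminins and type IV collagens around smooth muscle and under endothelium, rose as a group. Of 19 measured members, 9 rose, 1 fell and 9 did not pass (10 and 1 adjusted over the list alone), with a median log2 fold change of 0.343. Col4a2, a type IV collagen chain, went from 115.2 ± 12.8 to 205.8 ± 12.3 CPM (log2 fold change 0.84 ± 0.09, adjusted p = 3.60e-05), and Lama5 from 50.7 ± 4.99 to 95.6 ± 6.20 CPM. The member that fell was Lama2, the laminin chain of muscle basement membranes (log2 fold change -0.39 ± 0.09, adjusted p = 0.0251); its call was lost without WT 1, WT 5, Het 2, Het 4 or Het 5, with the highest adjusted p, 0.0633, without Het 2. By limma's camera the list had an adjusted p of 1.18e-07, and adjusted p = 0.0188 with an estimated correlation. It was the 1 list of 41 tested that passed both ways, also with the sex score and in the Xist-positive libraries (estimated correlation, adjusted p = 0.0142 and 0.0497), though not without WT 1 and WT 2 (0.0556). Adding the sex score left 6 members that rose, Lama5 and Col4a2 among them, and Lama2 did not pass (adjusted p = 0.315); 5 rose with the column-name number and 3 in the Xist-positive libraries.

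The other matrix lists had members that moved in both directions and did not pass as groups, except the collagen list without WT 1 and WT 2 (camera adjusted p = 0.038, and adjusted p = 0.227 with an estimated correlation) and the protease list with the sex score (0.0355, and 0.454), both higher in Het. Of 16 elastic fibre genes, 2 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.363). Eln went from 21870 ± 2311 to 30820 ± 3661 CPM (log2 fold change 0.49 ± 0.10, adjusted p = 0.00853), and Fbln5, which assembles elastic fibres, rose by 0.40 ± 0.08, while the microfibril protein Mfap5 fell by 0.70 ± 0.10. Fbn1, which encodes fibrillin-1, had a log2 fold change of 0.07 ± 0.08 (adjusted p = 0.708). Of 22 fibrillar collagen and collagen processing genes, 2 rose and 1 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.263). P4ha3, a collagen prolyl hydroxylase subunit, rose by 1.38 ± 0.26, and Col1a1 (0.38 ± 0.25, adjusted p = 0.454), Lox (0.25 ± 0.08, adjusted p = 0.102) and Col3a1 (-0.70 ± 0.24, adjusted p = 0.117) did not pass; Col3a1 passed without WT 5 (adjusted p = 0.0414) and with DESeq2 (0.0263), Lox with DESeq2 (0.0462), and Col1a1 without WT 1 and WT 2 (0.90 ± 0.19, adjusted p = 0.0292), with values from 0.06 to 0.90 over all settings. Of 14 proteoglycan and hyaluronan genes, 2 rose, Acan among them, and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.570), with a median of -0.029 and a mean of 0.158; Prelp, a leucine-rich proteoglycan, fell by 0.89 ± 0.15. Of 20 matrix proteases and inhibitors, 3 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.162); Plau, the urokinase plasminogen activator, rose by 1.20 ± 0.15 and the lysosomal protease Ctsb fell by 0.54 ± 0.07. With the sex score, Eln, Fbln5, P4ha3 and Prelp did not pass (adjusted p = 0.263, 0.154, 0.0841 and 0.156).

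**Figure D4:**
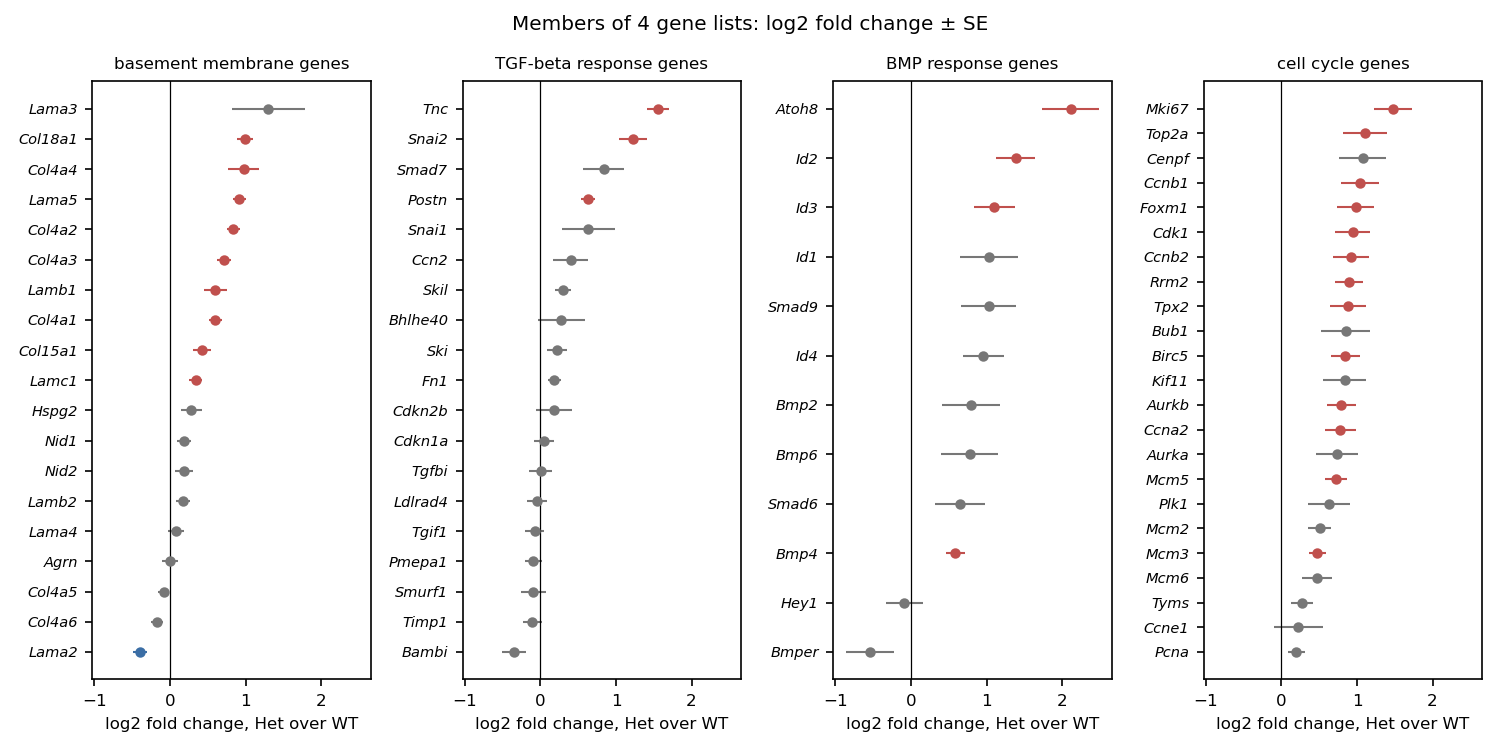
Log2 fold change (Het minus WT) ± SE of measured members of the basement membrane (19), TGF-beta response (19 of 20), BMP response (12) and cell cycle (23) lists, from 5 WT and 6 Het libraries. Red points rose, blue points fell and grey points did not pass an adjusted p of 0.05; all 23 cell cycle genes lie above 0.

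Transcripts induced by TGF-beta rose in part, and several BMP-induced genes rose. Of 20 TGF-beta response genes, 3 rose and none fell (5 and 0 adjusted over the list alone): Tnc, the matricellular protein Postn (0.63 ± 0.09, adjusted p = 7.86e-04) and the transcription factor Snai2 (1.22 ± 0.18, adjusted p = 0.00100). The textbook target Ccn2 (0.40 ± 0.23, adjusted p = 0.371) did not pass. The list had a camera adjusted p of 0.00562, and adjusted p = 0.159 with an estimated correlation. Of 12 BMP response genes, 4 rose and none fell (7 and 0 adjusted over the list alone): the transcription factor Atoh8 (2.11 ± 0.38, adjusted p = 0.00458), Id2 (1.39 ± 0.26, adjusted p = 0.00781) and Id3 (1.10 ± 0.27, adjusted p = 0.0356), both inhibitors of basic helix-loop-helix factors, and the ligand Bmp4 (0.59 ± 0.12, adjusted p = 0.0110). This list had a camera adjusted p of 9.48e-05, and adjusted p = 0.159 with an estimated correlation. The call of Id3 was lost without WT 1, WT 2, WT 5, Het 2, Het 3, Het 4 or Het 6, with the highest adjusted p, 0.103, without WT 2. With the sex score, the 3 TGF-beta response genes passed and none of the 12 BMP response genes did, at a median log2 fold change of 0.803 against 0.878. In the Xist-positive libraries Tnc passed, and Postn and Snai2 did not (adjusted p = 0.123 and 0.0855). None of the 12 BMP response genes passed there. Of these 12, 2 rose with the column-name number and 2 without WT 1 and WT 2.

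Among 18 TGF-beta ligands, receptors and carriers, 1 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 0.622). Ltbp2, a latent TGF-beta binding family member, rose by 0.66 ± 0.10, and Thbs1, the matricellular protein thrombospondin 1, fell by 0.80 ± 0.14. Tgfbr1, the type I receptor, was at 51.9 ± 6.26 CPM in WT and 40.7 ± 1.95 CPM in Het (log2 fold change -0.35 ± 0.09, adjusted p = 0.0375), a call lost when any library but WT 4 was left out, with the highest adjusted p, 0.108, without WT 2. The ligands Tgfb1 (0.08 ± 0.44), Tgfb2 (0.04 ± 0.13) and Tgfb3 (-0.19 ± 0.08) did not pass (adjusted p = 0.953, 0.914 and 0.189). With the sex score, Ltbp2, Thbs1 and Tgfbr1 did not pass (adjusted p = 0.0556, 0.213 and 0.283).

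Most smooth muscle contractile genes showed no detected difference. Of 22, none rose and 2 fell, the same counts adjusted over the list alone, and the list's camera adjusted p was 0.963, with a median of 0.025 and a mean of -0.003. Acta2 was at 27060 ± 1104 CPM in WT and 27880 ± 3143 CPM in Het (log2 fold change 0.04 ± 0.09, adjusted p = 0.847). The myosin heavy chain Myh11 (-0.05 ± 0.09), Tagln (-0.03 ± 0.11) and the transcriptional coactivator Myocd (0.26 ± 0.12) had adjusted p of 0.808, 0.934 and 0.258. Cnn1, calponin 1, fell by 0.51 ± 0.13 (adjusted p = 0.0346). The call of Cnn1 was lost without WT 1, 2 or 3 or Het 2, 3, 4, 5 or 6 (highest adjusted p 0.101, without WT 2). Cnn1 did not pass with the sex score (adjusted p = 0.474).

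Cell cycle genes were higher in Het, with a camera adjusted p of 3.52e-16 for the list, and adjusted p = 0.2 with an estimated correlation. All 23 measured members had a positive log2 fold change, with a median of 0.835; 13 rose and none fell (20 and 0 adjusted over the list alone). Mki67, a marker of dividing cells, went from 9.46 ± 4.28 to 26.2 ± 6.74 CPM (log2 fold change 1.48 ± 0.25, adjusted p = 0.00339), and the replication helicase subunit Mcm5 rose by 0.72 ± 0.15 (adjusted p = 0.00883). The number of members that rose moved with single libraries, to 3 without WT 2 or WT 3, 4 without Het 2, 5 without WT 1, Het 4 or Het 5, 6 without WT 5 or Het 6 and 17 without WT 4; it was 5 with the column-name number, 3 without WT 1 and WT 2 and 0 in the Xist-positive libraries. With the sex score 0 of the 23 passed in edgeR, all 23 remained higher and the median was 0.661; Mki67 and Mcm5 then had adjusted p of 0.115 and 0.0809.

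Lists of immune, stress and metabolic genes showed few calls. Of 10 cytokine and chemokine genes, 1 rose and 2 fell (camera adjusted p = 0.676; median -0.135, mean 0.042), and of 18 interferon response genes and 16 immediate early and stress genes none passed (0.498 and 0.676). Of 18 unfolded protein response genes 1 rose (0.884), of 13 Notch pathway genes 2 rose (0.263) and of 16 angiotensin and vasoactive genes 1 rose (0.288). Notch3, the Notch receptor of vascular mural cells, rose by 0.86 ± 0.13 (adjusted p = 0.00138; 0.0841 with the sex score). The angiotensin receptor Agtr1a (0.19 ± 0.17, adjusted p = 0.601) and the endothelial nitric oxide synthase Nos3 (-0.47 ± 0.23, adjusted p = 0.270) did not pass. Adjusted over the list alone, the counts were those over all genes for these 6 lists, except 3 that rose in the Notch list. None passed among 30 nuclear oxidative phosphorylation, 19 fatty acid oxidation, 16 glycolysis and 18 cholesterol synthesis genes, over all genes or adjusted over the list alone (camera adjusted p = 0.834, 0.884, 0.855 and 0.884). Of 7 mitochondrially encoded genes 1 rose (2 adjusted over the list alone), with a median of 0.445; none rose without WT 1, WT 2, WT 3, Het 2, Het 5 or Het 6 or with the sex score, and 2 rose without WT 5. The camera adjusted p was 0.00417, and adjusted p = 0.564 with an estimated correlation, and the list's call was lost without WT 1 and WT 2 (0.255, median 0.157). By camera with the sex score and in the Xist-positive libraries, nuclear oxidative phosphorylation (adjusted p = 0.00149 and 0.00371; 0.026 without WT 5) and fatty acid oxidation genes (0.00214 and 0.00527) were higher in Het, as were fat cell and brown fat markers. With an estimated correlation in those fits, neither metabolic list passed (adjusted p = 0.676, 0.714 and 0.928, and 0.641 and 0.671).

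Of the marker lists of other cell types that an arch dissection can hold, the erythroid, epithelial and macrophage lists passed camera, none of them with an estimated correlation. Erythroid markers were lower in Het, with a median log2 fold change of -0.745 over 7 genes: none passed over all genes and 3 fell adjusted over the list alone (camera adjusted p = 9.07e-04, and adjusted p = 0.499 with an estimated correlation). The globin Hbb-bt, which shares sequence with the other beta globin genes, was at 125.5 ± 45.4 CPM in WT and 70.3 ± 25.0 CPM in Het (adjusted p = 0.125); it passed in 3 of the settings tried, with the lowest adjusted p, 0.00333, with surrogate variables. The erythroid list did not pass with the sex score (adjusted p = 0.167, median -0.332) or in the Xist-positive libraries (0.0836, median -0.352). Of 5 epithelial markers 2 fell, over all genes and adjusted over the list alone, at a median of -0.484 (camera adjusted p = 0.00678, and adjusted p = 0.2 with an estimated correlation; 0.0547 with the number in the column names as a covariate, where the median was -0.057 and 1 fell). Krt18, a keratin of simple epithelia, went from 263.2 ± 41.9 to 111.4 ± 24.8 CPM (log2 fold change -1.24 ± 0.14, adjusted p = 1.27e-04). Macrophage markers had a median of 0.433 over 15 genes, none of which passed over all genes or adjusted over the list alone (camera adjusted p = 0.0109, and adjusted p = 0.711 with an estimated correlation). The macrophage call was lost without WT 2 (0.129, median 0.23), Het 1 (0.103), Het 3 (0.0708) or both WT 1 and WT 2 (0.376, median 0.1).

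The other marker lists did not pass camera in all 11 libraries, but some did once sex was handled. Of 5 skeletal muscle markers 2 fell (adjusted p = 0.192), Tnni2 and the troponin Tnnt3, which fell by 1.63 ± 0.23; with the sex score Tnnt3 had an adjusted p of 0.0705. Of 6 pericyte markers 2 rose (0.192), Notch3 among them. Of 12 adventitial fibroblast markers 2 rose and 2 fell (0.884), Mfap5 and Pi16, which fell by 0.62 ± 0.10 (adjusted p = 0.116 with the sex score). None of 14 endothelial, 6 lymphatic endothelial, 6 mast cell, 6 T cell and thymocyte, 5 B cell, 12 fat cell, 6 Schwann cell, 4 sympathetic neuron, 7 mesothelial and 11 anterior position genes passed over all genes (camera adjusted p = 0.599, 0.963, 0.884, 0.718, 0.884, 0.963, 0.363, 0.884, 0.570 and 0.855). Fat cell (adjusted p = 6.82e-04 and 2.30e-04) and brown fat markers (0.00248 and 0.00127) were higher in Het with the sex score and in the Xist-positive libraries, bone markers were lower (0.00157 and 0.00371), and endothelial markers were higher with the score (0.0285; 0.0847 in the Xist-positive libraries). None of these 4 lists passed with an estimated correlation in the same fits (adjusted p = 0.559 and 0.665 for both fat lists, 0.173 and 0.434 for bone, 0.559 and 0.671 for endothelium). The T cell and thymocyte median was 0.891, at an adjusted p of 0.718, and the list passed with the column-name number (7.03e-05, and adjusted p = 0.338 with an estimated correlation). Of 10 heart muscle markers and 11 brown fat markers 1 rose in each (0.963 in both), of 7 cartilage markers 1 rose, Acan, and 1 fell (0.596), and of 4 bone markers 1 fell (0.162). Adjusted over the list alone, counts differed for adventitial fibroblasts (3 rose), endothelium (1 rose and 2 fell), heart muscle (2 rose and 2 fell), brown fat (2 rose and 1 fell) and sympathetic neurons (1 fell). Too few members were measured to test the neutrophil (2), thyroid and parathyroid (1) and posterior Hox (1) lists.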

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

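The tests of the column-name number, of the cell cycle genes and of the MHC class II genes against leukocytes, and the MHC class II list itself, were chosen only after the result was seen. Of 156 groups of values examined, 14 held a library far from the others of its group, where about 1 in 20 would by chance. In WT these were Tgfbr2 in WT 5 (48.8 CPM, others 38.3 to 41.0), Mki67 in WT 4 (16.9, others 5.90 to 8.60), Acan in WT 4 (9.92, others 4.26 to 4.83), Snai2 in WT 4 (9.41, others 5.80 to 6.73), Agtr1a in WT 1 (27.1, others 14.1 to 17.8), Kcnj15 in WT 5 (79.1, others 58.3 to 64.2) and Thbs1 in WT 5 (56.4, others 40.7 to 44.2). In Het they were Ccn2 in Het 5 (272 CPM, others 115 to 173), Tagln in Het 1 (3713, others 2751 to 3090), Col1a1 in Het 6 (11178, others 5751 to 7418), Cd74 in Het 1 (144, others 91.4 to 106), Nppc in Het 2 (1.59, others 0.488 to 0.882) and Dkk2 in Het 2 (14.3, others 5.98 to 7.96). The total of Het 5 was 18883711 counts, against 13162449 to 15153484 in the other Het libraries. Ddx3y, used in the sex score, reached 107.98 CPM in Het 5 and at least 88.15 CPM in Het 3, 4 and 6, and 0 counts in the other 7 libraries.

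The 742 genes called between Het and WT exceed what regrouping gave. Of 100 splits of the 11 libraries into 5 and 6, drawn from 462 possible, only the real one called as many, and the highest other called 5. Chance is therefore unlikely, at 1 of 100 splits, the smallest share that this draw can give. If the sex make-up of the groups were the whole difference, Y-positive and Xist-positive Het libraries would differ by about 1.5 times the Het minus WT change; the median ratio was 0.066, where 14 other splits of the Het libraries had an SD of 0.091. If the number in the column names were the whole difference, Het libraries with a 6 and with a 7 would differ by about 2.14 times that change, and the median ratio was -0.01 (SD of other splits 0.093). Both ratios were taken over genes called in these same libraries. The test favours genes with small differences within Het, which lowers both ratios, so they cannot decide these questions alone. A carried-over region around the targeted Tgfbr2 allele that changed many neighbours would be seen as more calls nearby. Of 204 genes within 10 Mb, 7 were called (3.43 percent), against 735 of 14553 others (5.05 percent, one-sided Fisher exact p = 0.893). No excess of calls was seen there, but the share over the window cannot exclude such an effect on single neighbours. An effect of the mutant allele is a candidate explanation, as a hypothesis. Litter, effects of sex or of the number on part of the genes, and a carried-over region for single neighbours stay open.

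Cell cycle genes were higher in Het by a median of 0.835 over 23 genes. The sex make-up would need a ratio near 1.5 between Y-positive and Xist-positive Het libraries, and the median was 0.169 (SD of other splits 0.234). As 13 of the 23 genes were called in these libraries, the limit given for the ratios of the called genes holds here too. With the sex score as a covariate the median was 0.661 and 0 genes passed, so an effect of sex stays open for this list. If dividing blood or thymus cells were the whole source and a leukocyte score tracked them, that score as a covariate would take the change away. The median stayed at 0.821 (median SE of a gene 0.243) with the T cell score, with 10 genes past the threshold. With the pan-leukocyte score it was 0.832 (0.239), with 11 past. These scores mark leukocytes, dividing or not, and a noisy score takes away less. The fits therefore cannot exclude such a source. The T cell genes had a fitted median of 0.891, above that of the cell cycle genes. As a mean of log2 CPM per library the T cell list was higher by 0.398 (SD 1.033 in WT, 1.747 in Het). The pan-leukocyte list was higher by 0.066 (SD 0.5 and 0.462), against 0.813 for the cell cycle list. A source in such cells, for all or part of the change, stays open. More division of resident cells in Het may account for it, as may a difference in growth between animals, which was not tested.

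MHC class II genes were lower in Het by a median of -1.709 (SE 0.300) over 8 genes. The SEs of medians in this paragraph are over list members, so they do not measure the spread between animals. The rule chosen was that fewer antigen-presenting leukocytes would bring the medians of their markers to -0.855 or lower. The macrophage median was 0.433 (SE 0.071), with 0.23 without WT 2 and 0.1 without WT 1 and WT 2. The pan-leukocyte median was 0.135 (SE 0.134), and that of 4 dendritic cell markers, the lowest of the 3 lists in the rule, -0.02 (SE 0.294). Of 10 dendritic cell markers listed, only these 4 were measured. Their log2 fold changes ran from -0.58 to 0.49, none past the threshold, so this median does not show that dendritic cells were unchanged. B cell markers, which were not in the rule, had a median of -0.394 over 5 genes. The sex make-up would need a ratio near 1.5, and the median was 0.188 (SD of other splits 0.134). As 7 of the 8 genes were called in these libraries, the limit given for the ratios of the called genes holds here too. Lower expression of the MHC class II program per cell may be the reason, as a hypothesis. A loss of B cells, of a subset of leukocytes or of a rare cell type that these lists do not mark stays open.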

How the results depend on the processing

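The number in the column names, the Xist-positive libraries, the fit without WT 1 and WT 2 and DESeq2 with the sex score were chosen only after the data were seen, as were the split counts per list, the pan-leukocyte score for the cell cycle genes and the estimated correlation in fits other than that of all libraries without covariates; all other settings were planned. The count of 742 genes became 1295 with DESeq2 (all 742 shared), 1290 at an adjusted p under 0.1, 122 with the sex score, 339 with DESeq2 and the sex score, 34 in the Xist-positive libraries, 415 with the column-name number, 443 without WT 1 and WT 2, and 465 (without WT 2) to 854 (without WT 4) with 1 library left out. The sex fits use fewer libraries or a confounded term, and their standard errors widened; the cause of the other shifts was not tested. As a replicate block, without Het 6, the replicate numbers gave 321 genes, 308 of them shared. Same-numbered libraries deviated together with r from -0.214 to 0.059 and none correlated best with its own number. No pairing by number was therefore seen, though one that leaves no such correlation cannot be excluded. The called genes tested kept their direction in every setting. The 8 lists became 1 with an estimated correlation, 8 with limma's fry (5 shared; mitochondrially encoded, macrophage and erythroid lists lost at adjusted p = 0.187, 0.427 and 0.0972, and angiotensin and vasoactive, pericyte and skeletal muscle lists gained at 0.0223, 0.0281 and 0.0447), 14 with the sex score (7 shared; matrix protease, nuclear oxidative phosphorylation, fatty acid oxidation, endothelial, brown fat, fat cell and bone lists gained), 12 in the Xist-positive libraries (7 shared, and these gained but for the protease and endothelial lists), 8 with the column-name number (T cell gained, epithelium lost), 8 without WT 1 and WT 2 (collagen and skeletal muscle gained, macrophage and mitochondrially encoded lost) and 7 to 9 with 1 library left out. With an estimated correlation, 1 list, basement membrane, was called with the sex score, in the Xist-positive libraries, with the column-name number and without WT 5, and 0 without WT 1 and WT 2. In 44 of 100 splits of the libraries at least 8 lists were called (highest other 16), so chance cannot be excluded for that number. Single lists with a p as small in under 5 splits, the real one counted, were basement membrane (1), TGF-beta response (1), BMP response (2) and cell cycle (4). These split counts were not adjusted over the 41 lists, so they do not exclude chance for a single list. Tgfbr2 stayed between -0.18 and -0.0044, never past the threshold. Of the named genes, 58 were called; over 2335 gene and setting pairs, 141 lost a call (30 with 1 library left out, too few as a measure of stability, since part of the genes that lost a call this way were not named), 7 gained one and 22 reversed, none of these called in any setting. The reversed values were, for Tgfb1, -0.56 with the sex score, -0.0401 with the T cell score, -0.72 in the Xist-positive libraries, -0.57 with DESeq2 and the sex score, and -0.23 to 0.355 leaving out 1 library; for Tgfb2, -0.005 with the column-name number and -0.0609 to 0.107 leaving out 1; for Acta2, -0.035 and -0.0026 to 0.0893 likewise. Myh11 had 0.0472 with the sex score, 0.0515 in the Xist-positive libraries, 0.0444 with DESeq2 and the sex score and -0.093 to 0.0031 leaving out 1, and Tagln 0.0742, 0.094, 0.0715 and -0.0977 to 0.0647 in the same order. Depth left levels under 0.155 to 0.229 CPM undetermined.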

Other observations

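The lists in this part were put together after the called genes were seen, so no group test is given for them. MHC class II genes fell nearly as a whole: of 8 measured, 7 fell, Cd74, H2-Aa, H2-DMb1, H2-Ab1 (-1.67 ± 0.19, SE), H2-Eb1 (-1.86 ± 0.16), H2-DMa (-0.999 ± 0.148) and Ciita (-1.88 ± 0.28), the transcriptional activator of the class II genes, and 1 did not pass. With the sex score, H2-DMa had an adjusted p of 0.0809 and the other 6 passed. In the Xist-positive libraries H2-Ab1, H2-DMa and Ciita did not pass (adjusted p = 0.0657, 0.126 and 0.15). Of 9 MHC class I genes none passed, with a median of 0.061. Ciita and H2-DMa overlap other genes on the opposite strand in 3.5 and 10.4 percent of their exon bases, so their reads are uncertain.

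Growth factor modulators moved in both directions. Among 9 secreted Wnt inhibitors, Sost (1.39 ± 0.14) and Sfrp1 (0.79 ± 0.12) rose and Wif1, Frzb (-0.71 ± 0.15) and Dkk2 (-0.98 ± 0.22) fell. Igf1, a growth factor, fell from 1023 ± 178.9 to 446.5 ± 96.5 CPM (-1.20 ± 0.14, adjusted p = 1.88e-04), while of its binding proteins Igfbp2 and Igfbp7 (0.60 ± 0.13) rose and Igfbp4 (-0.52 ± 0.09) fell. Of 9 feedback inhibitors and targets of ERK signalling, Spry2 and Spry4 (1.16 ± 0.21) rose and none fell. With the sex score, Sfrp1, Frzb, Dkk2, Igfbp4, Igfbp7 and Spry4 did not pass (adjusted p = 0.0602, 0.365, 0.378, 0.172, 0.278 and 0.0781), and Frzb was also lost with the column-name number (0.0629). Sost, Igf1 and Igfbp2 passed with the sex score, and Igf1 did not pass in the Xist-positive libraries (adjusted p = 0.123).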
